A study of Mus musculus with 4 samples.

How the data were processed

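Small RNA was sequenced from total RNA of bone marrow taken from C57BL/6 mice at postnatal day 8, in 2 wild-type (WT) libraries and 2 libraries of Dnmt2-deficient mice (Dnmt2 KO). Per the labels' protocols, RNA was isolated with Trizol, treated with DNase I and end-repaired with T4 polynucleotide kinase, an enzyme that can make phosphate or hydroxyl ends of fragments fit for ligation, and a commercial small RNA kit with size selection was used. CASAVA 1.8.3 and Bowtie are named per the submitters' processing notes. The alignment settings, the reference set of tRNA genes, the genome build and the treatment of reads that match several tRNA genes are not given in the sources used here, nor are the anticodons within a family such as Val.

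The deposited data are 48 tables of signal, per the file headers one column of coverage per library and strand. Each table holds the coverage at every position of a tRNA family, for the WT and the Dnmt2 KO library of one replicate number. The values carry a normalization by one constant per library that no header or label explains. Every value above 0 was a whole multiple of one step per library (100% of values, within 0.01 of a step), 6.57e-06 in WT replicate 1, 1.35e-05 in WT replicate 2, 1.31e-05 in Dnmt2 KO replicate 1 and 2.80e-05 in Dnmt2 KO replicate 2. This step is read here as the worth of one read, which gives the depth behind each value. Coverage counts one read at every position it spans, so no count model was used. Levels set between libraries depend on the unexplained constant, and shares within a family do not. Rows are labelled from 0 and are counted here from 1, so that the row labelled 0 is position 1. Tables have 70 to 85 positions, and their relation to the standard tRNA numbering is not given in the sources used here. A window such as the anticodon loop is therefore placed only approximately in families of unusual length.

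Read depth was estimated as the reads over the highest position of each family, summed over 23 families. This depth is a lower bound on the tRNA reads only if no read counts in several families. It was 423186 in WT replicate 1, 337091 in WT replicate 2, 267920 in Dnmt2 KO replicate 1 and 220277 in Dnmt2 KO replicate 2. A floor of 3 reads corresponds to a signal of 1.97e-05, 4.05e-05, 3.94e-05 and 8.41e-05 in the same order. Floors and the exact (Clopper-Pearson) 95% binomial intervals used for read shares cover counting error only, since reads without molecular identifiers are not independent molecules.

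Forward-strand coverage was used throughout. The table for all glycine tRNAs equals the sum of its GlyGCC and non-GCC parts and was left out, which leaves 23 families. For each family, coverage was summed over positions (family total), and the share of that sum was taken at positions 32 to 38 (anticodon loop share) and at positions 1 to 34 (5′ share). Family totals and single positions were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) on log2(value + pseudocount), with a pseudocount of 0.001 for totals and 1e-04 for positions, and the shares on the log2 odds with the pseudocount of 0.001 on both sides. Fold changes are on that scale and understate the change of low totals and positions, whereas a share whose coverage is near the pseudocount can also move with the family total. The design assumed count or normalized tables, and the signal found in the tables decided for limma. Genotype was the sole term, tests were two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05 was applied over the 23 families or over the 1656 positions with coverage, 42 positions having none. Family sets were tested with limma's fry and with camera, at a preset correlation of 0.01 and with an estimated one. A comparison of 2 against 2 libraries by exact permutation cannot go below a two-sided p of 0.333, so single values are given without such a test. The labels do not state that replicates are separate animals, so p-values measure only the spread between these libraries, which may be technical.

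Before the data were examined, the tests, the family sets, the windows, most alternatives and the rule for naming families were fixed. Named in every comparison are Asp, GlyGCC, Val and Gly_non_GCC. To these come up to 10 families that rose and 10 that fell past the threshold or, where none passes, the 4 with the largest estimate in each direction, with values only. For single positions the rule names, in each such family, the position of highest coverage per genotype and the position with the largest estimate among those where both Dnmt2 KO libraries move the same way. Alternatives were leaving out each library, the replicate number as a block, libraries rescaled to one total or one median family, other pseudocounts, windows and low-value filters, the mean or highest position in place of the sum, the whole glycine table, and sets without single members. Reading the row labels as positions, a variance trend, keeping positions without coverage, and rescaling libraries before the replicate numbers were compared were added after the data had been seen.

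The fits were tested on simulated data made from the means over libraries and their depths, with 50 draws and a spread drawn independently for each family or position. With the median spread between libraries as observed, the test over 23 families recovered 35% of 4-fold and 89% of 16-fold changes, and the test over 1656 positions 2.92% and 39.1%. With counting noise alone it recovered 100% of both over families, and 90.3% and 97.7% over positions. In the data, deviations of same-numbered libraries from their genotype means correlated at 0.862 across families, which the independent draws leave out. The recovered shares may therefore not hold for these libraries. Family counts were drawn from summed coverage, in which a read counts at every position it spans. Counting noise over families was therefore understated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The transcript of Dnmt2 itself was not analysed here, since the tables hold tRNA coverage, and the genotype of each library rests on its label.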

Results

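Dnmt2 is an RNA cytosine methyltransferase that methylates cytosine 38 of tRNA-Asp-GTC, tRNA-Gly-GCC and tRNA-Val-AAC, in the anticodon loop, where stress-activated ribonucleases cut tRNAs into fragments. The series sequenced small RNA from bone marrow, the blood-forming tissue, of mice at postnatal day 8, with 2 WT and 2 Dnmt2 KO libraries. Coverage along each tRNA family shows where its fragments lie, and the summed coverage rises with both their number and their length. Genome coordinates of the tRNA genes are not given in the sources used here, and families are named as in the tables.

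Fragments of a few families made up most of the coverage. GlyGCC held 56.7% and 40.4% of the summed coverage in WT replicates 1 and 2, and 63.4% and 41.7% in Dnmt2 KO replicates 1 and 2. Glu held 22.2% and 38.1% in the WT libraries and 15.3% and 29.6% in the Dnmt2 KO libraries. The summed coverage was 116 ± 39.5 deposited units in WT and 150 ± 56.9 in Dnmt2 KO (SD, n = 2 each), and the Dnmt2 KO library held 1.25 times the WT library among those numbered 1 and 1.33 times among those numbered 2. The WT libraries held 423186 and 337091 reads over the peaks of the families, and the Dnmt2 KO libraries 267920 and 220277. The depth ranged from 236284 reads at the peak of GlyGCC in WT replicate 1 to 1 read at the peak of the suppressor family Sup in Dnmt2 KO replicate 2.

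The comparison of family totals asked whether bone marrow without Dnmt2 gave more or less fragment coverage of each tRNA family. Among the families of Dnmt2 substrates, GlyGCC coverage was 53.8 ± 5.84 units in WT and 74.5 ± 6.89 in Dnmt2 KO (SD, n = 2), Asp coverage was 3.01 ± 0.502 and 4.06 ± 0.954, and Val coverage was 3.63 ± 2.28 and 4.49 ± 4.03. Gly_non_GCC, the glycine tRNAs that share the amino acid of a substrate but not its anticodon, had 4.53 ± 0.373 units in WT and 6.75 ± 0.211 in Dnmt2 KO. The largest estimates were those of His, at 2.77 ± 0.00911 and 6.97 ± 3.20 units, and Gln, at 0.641 ± 0.271 and 1.59 ± 1.13 units. Ala followed with 0.544 ± 0.256 and 1.25 ± 1.16 units, and Phe with 0.0150 ± 0.00331 and 0.0279 ± 0.00425 units. Glu, at 37.1 ± 24.9 and 36.6 ± 28.0 units, and Sup, with 1 to 5 reads at its peak per library, had the sole estimates below 0. Without WT replicate 2 both log2 differences turned above 0, to 0.66 for Glu and 0.21 for Sup.

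None of these differences passed the test with genotype as the sole term. With limma, 0 of 23 families passed the threshold (lowest adjusted p = 0.973), and 0 had an unadjusted p under 0.05. With the replicate number added as a block, His and Gln passed, as given below. The labels do not say what a number marks, so that fit is a hint only. As deposited, 21 estimates were above 0 and 2 below, with a median log2 difference of 0.47 over all families, which became 0.10 with libraries rescaled to one total (16 above and 7 below) and 0.031 with one median family (13 above and 10 below). Relative to the median family, the log2 difference was 0.78 for His, 0.70 for Gln, 0.40 for Ala, 0.40 for Phe, 0.11 for Gly_non_GCC, 0.00 for GlyGCC, −0.050 for Asp, −0.38 for Val, −0.56 for Glu and −0.60 for Sup. The SE of the log2 difference was 0.73 for His, 0.86 for Gln, 0.70 for Asp, 0.68 for GlyGCC and 1.01 for Val, and the 95% limma interval of His ran from −0.55 to 3.06. In 5 families (Asp, GlyGCC, Gly_non_GCC, His and Phe) both Dnmt2 KO libraries lay above both WT libraries as deposited and in 0 families below. Together these are 21.7% of families, where exchangeable libraries would give 33.3%. A shift shared by same-numbered libraries makes the genotypes overlap more often, so the low share is no evidence that they are alike. Between replicate numbers these 5 families did not pass limma's threshold as deposited (lowest adjusted p = 0.424, for His).

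As deposited, several families differed between the replicate numbers in both genotypes, so ratios within a number stand beside the pooled values. Lys, for example, had 2.94 and 8.42 units in WT replicates 1 and 2 and 2.91 and 13.9 units in Dnmt2 KO replicates 1 and 2. The Dnmt2 KO to WT ratio in libraries numbered 1 and 2 was 1.70 and 3.34 for His, 1.77 and 2.87 for Gln, 1.40 and 1.37 for GlyGCC, 1.27 and 1.41 for Asp, 1.44 and 1.55 for Gly_non_GCC, and 0.813 and 1.40 for Val. In 17 families the ratio was above 1 in both numbers as deposited, and in 0 families it was below 1 in both. Val was lower in Dnmt2 KO than in WT once libraries were rescaled to one total (log2 difference −0.27) or one median family (−0.35), and Asp was at −0.019 with one median family. Without Dnmt2 KO replicate 2, the log2 difference of Ala turned from 0.87 to −0.26 and that of Val from 0.092 to −0.99.

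**Figure D1:**
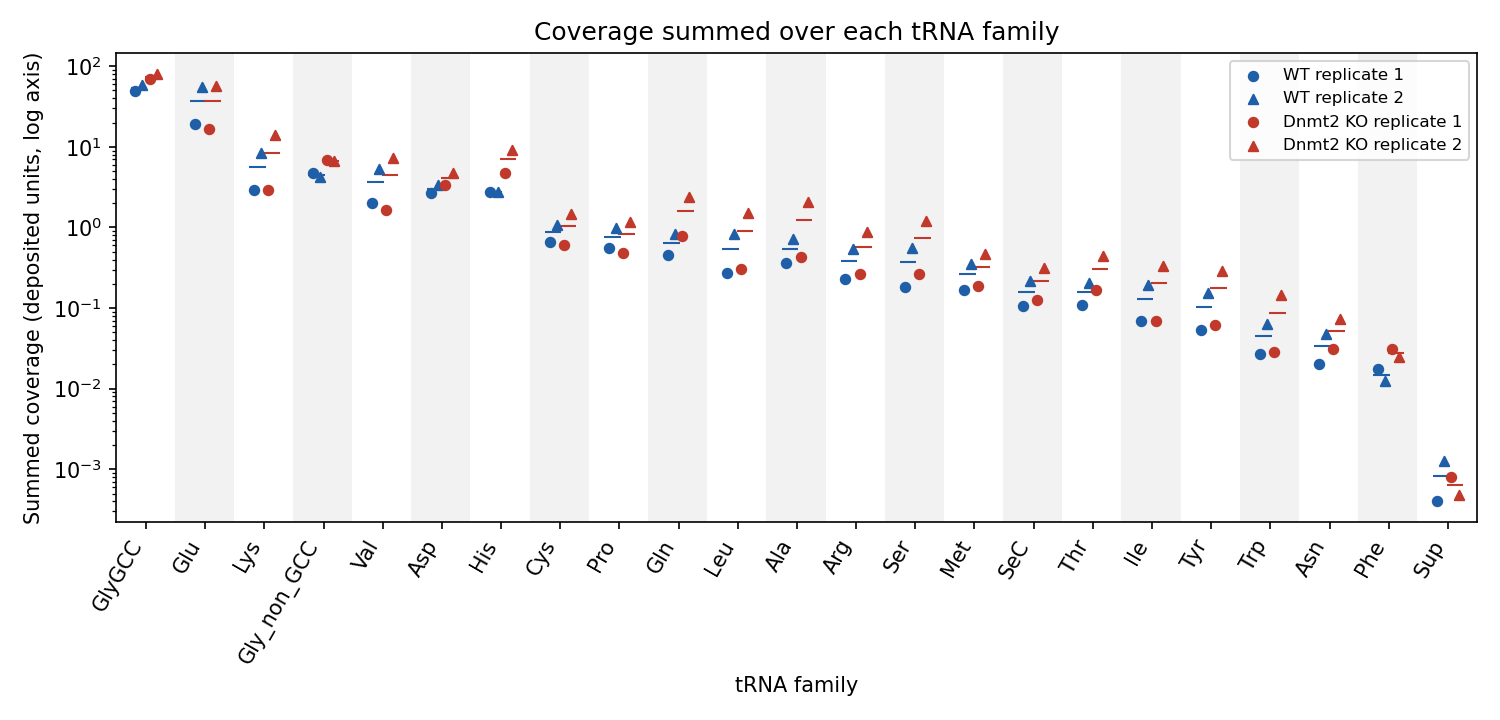
Coverage summed over each of 23 tRNA families, in deposited units on a log axis, for each library. Points are single libraries, short lines are the means of 2 libraries, and families are ordered by their WT mean. In Lys, Leu and Val the libraries numbered 2 lie above those numbered 1 in both genotypes, while the 4 values of GlyGCC lie between 49.7 and 79.3 units.

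Families were grouped into 5 sets fixed in advance. Of the 3 families with Dnmt2 substrates, 0 rose and 0 fell, 0 when adjusted over the list alone, and their mean log2 difference was 0.33 against 0.52 in the other 20 families. The median of this set was 0.42 and fry gave an upward direction (adjusted p = 0.720), while camera, which compares the set with the other families, gave a downward one (adjusted p = 0.952, and adjusted p = 0.999 with an estimated correlation). The set of 4 families that carry queuosine at the wobble position (Asp, Asn, His, Tyr) had a mean of 0.70, with His at 6.97 and Tyr at 0.176 ± 0.163 units in Dnmt2 KO (SD, n = 2). The 5 families often seen as 5′ fragments in blood-forming tissue (GlyGCC, Glu, Val, Lys, His) had a mean of 0.42. The 3 families with a long variable arm (Leu, Ser, SeC) had a mean of 0.57, and the 8 families with members that carry inosine at position 34 a mean of 0.50, where Ser had 0.374 ± 0.267 units in WT and 0.740 ± 0.672 in Dnmt2 KO. No member of any of these sets passed the test, over all families or adjusted over the list alone, and fry gave an adjusted p of 0.720 for each. The mean of the queuosine set was 0.088 without Dnmt2 KO replicate 2 and 0.27 with one median family. Also without Dnmt2 KO replicate 2, the long variable arm set had a mean of −0.40 and the inosine set one of −0.47. The set often seen as 5′ fragments had −0.32 there. For the substrate set the mean was −0.14 without Dnmt2 KO replicate 2, −0.038 with libraries rescaled to one total and −0.11 with one median family.

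The anticodon loop share asked how much of the coverage of a family lay at positions 32 to 38, around the cytosine that Dnmt2 methylates. Asp had 7.04% ± 0.809 of its coverage there in WT and 5.75% ± 0.262 in Dnmt2 KO (SD, n = 2), GlyGCC 3.70% ± 0.604 and 3.12% ± 0.768, and Val 5.06% ± 0.0983 and 4.83% ± 0.423. Gly_non_GCC had 3.06% ± 0.479 and 2.66% ± 0.0338. Phe had the lowest estimate, with 2.10% ± 0.977 in WT and 0.905% ± 0.643 in Dnmt2 KO, followed by Ser, with 1.67% ± 0.297 and 1.44% ± 0.685, Leu, with 3.42% ± 0.624 and 2.70% ± 0.163, and Trp, with 2.14% ± 0.168 and 2.15% ± 0.889, whose estimate on the log2 odds scale was −0.32 although the means were alike. On the other side stood Tyr, with 2.45% ± 0.233 and 3.67% ± 1.59, Arg, with 8.00% ± 0.260 and 9.68% ± 0.0521, Gln, with 13.6% ± 4.45 and 15.7% ± 3.59, and Lys, with 7.10% ± 0.270 and 7.58% ± 0.914.

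With limma, 0 of 23 families passed the threshold for the loop share, and 1 had an unadjusted p under 0.05, namely Phe (log2 odds difference −0.93, SE 0.28, adjusted p = 0.408), which has 32 to 143 reads at its peak per library. The loop coverage of Phe, at most 0.000420 units, lies below the pseudocount of 0.001, and one common share in all libraries would already give Phe a difference of −0.65 and Trp one of −0.22. The log2 odds difference was −0.31 (SE 0.23) for Asp, −0.27 (SE 0.29) for GlyGCC and −0.072 (SE 0.22) for Val. In 17 families the estimate was below 0 and in 6 above. One common share would also give −0.16 in Ala, −0.097 in Ser and −0.062 in Thr, but 0.13 in Sup. For Asp and GlyGCC it would give −0.0017 and −0.00021. The count of estimates below 0 can therefore partly reflect the pseudocount. Both Dnmt2 KO libraries lay below both WT libraries in 8 families and above in 1, together 39.1% of families where exchangeable libraries would give 33.3%. Within numbers 1 and 2, the ratio of the shares was 0.860 and 0.780 for Asp, 0.785 and 0.886 for GlyGCC, 0.883 and 1.03 for Val, and 0.967 and 0.162 for Phe. Over the substrate set the mean was −0.22 against −0.13 in the other 20 families, with 0 of 3 members past the test, 0 adjusted over the list alone, and a fry p of 0.299 for the set itself. The difference from the other families had a camera p of 0.431, and p = 0.616 with an estimated correlation. With the window at positions 34 to 40 the estimate of Asp turned to 0.017 and that of Val to 0.079.

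The 5′ share asked from which side of the anticodon the fragments came. In WT, coverage at positions 1 to 34 was 97.9% ± 1.04 of GlyGCC, 92.1% ± 1.43 of Val, 94.4% ± 1.13 of Gly_non_GCC and 98.8% ± 0.815 of His (SD, n = 2), so that these families were seen almost wholly as 5′ fragments. Asp was the opposite, with most of its coverage 3′ of the anticodon, and its 5′ share was 24.5% ± 7.06 in WT and 13.5% ± 4.21 in Dnmt2 KO. In Dnmt2 KO, the share of GlyGCC was 97.5% ± 2.34, that of Val 88.2% ± 2.91, that of Gly_non_GCC 95.3% ± 2.76 and that of His 99.2% ± 0.477. Ala, at 77.4% ± 2.69 and 86.3% ± 6.05, Ser, at 80.1% ± 14.5 and 86.5% ± 10.9, and Leu, at 47.1% ± 3.75 and 58.2% ± 19.6, had the largest estimates above 0 together with His. Ile, at 45.7% ± 16.7 and 34.1% ± 8.87, and Cys, at 95.9% ± 2.10 and 93.9% ± 2.04, stood with Asp and Val at the low end. The log2 odds difference of Ile moved from −0.69 to −0.0050 without WT replicate 1, and that of Cys from −0.65 to −0.078 without WT replicate 2. That of Ser turned from 0.73 to −0.32 and that of Leu from 0.68 to −0.16 without Dnmt2 KO replicate 2. That of His turned from 0.45 to −0.31 without WT replicate 2.

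**Figure D2:**
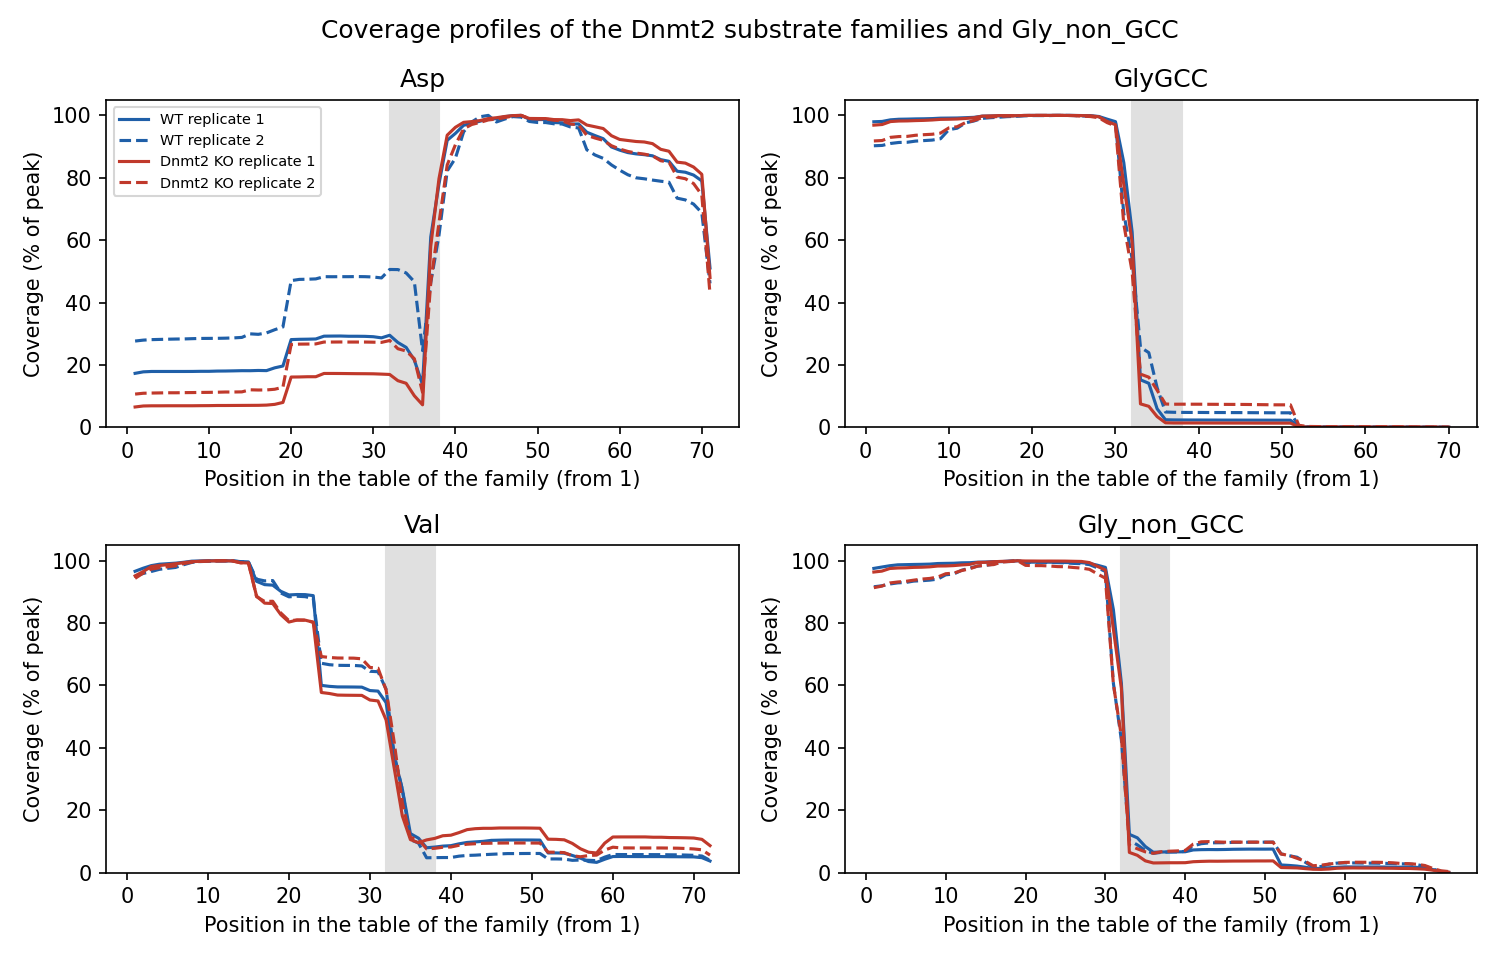
Forward-strand coverage along Asp, GlyGCC, Val and Gly_non_GCC, as a percentage of the highest position in each library, against the position in the table counted from 1. Blue lines are WT and red lines Dnmt2 KO, dashed for replicate 2, and the grey band marks positions 32 to 38. GlyGCC and Gly_non_GCC lose most of their coverage between positions 30 and 38 and Val loses it in steps, whereas Asp gains coverage from within the band on, with a lower 5′ plateau in each Dnmt2 KO library than in the WT library of the same number.

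With limma, 0 of 23 families passed the threshold for the 5′ share (lowest adjusted p = 0.928), and 0 had an unadjusted p under 0.05. Asp had the largest estimate in size, a log2 odds difference of −1.06 (SE 0.68, 95% interval −2.46 to 0.35, adjusted p = 0.928), with 19.5% and 29.5% in the WT libraries and 10.5% and 16.5% in the Dnmt2 KO libraries. The ratio of the Asp shares was 0.542 in number 1 and 0.560 in number 2, those of Val were 0.945 and 0.969, and those of GlyGCC 1.01 and 0.987. The log2 odds difference was −0.64 (SE 0.67) for Val, 0.087 (SE 0.77) for GlyGCC and 0.95 (SE 0.68) for Ala. Without Dnmt2 KO replicate 1 that of Val was −0.35, and without Dnmt2 KO replicate 2 that of Ala was 0.41. That of GlyGCC was −1.10 without Dnmt2 KO replicate 1 and 1.28 without Dnmt2 KO replicate 2. Both Dnmt2 KO libraries lay below both WT libraries in 3 families (Asp, Pro and Val) and above in 1 (Ala). Together these are 17.4% of families, where exchangeable libraries would give 33.3%. Over the substrate set the mean log2 odds difference was −0.54 against 0.00 in the other 20 families, and 0 of 3 members passed, also 0 adjusted over the list alone. The fry p of the set was 0.0946, camera's was 0.0814, and camera's with an estimated correlation was p = 0.206. The set value rested largely on Asp, without which the mean was −0.28 and the fry p 0.614. Without Dnmt2 KO replicate 1 the fry p was 0.0305 (mean −0.71), and with the window at positions 1 to 30 it was 0.0467 (mean −0.44), the lowest p over its alternatives being 0.0305 and the highest 0.614.

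**Figure D3:**
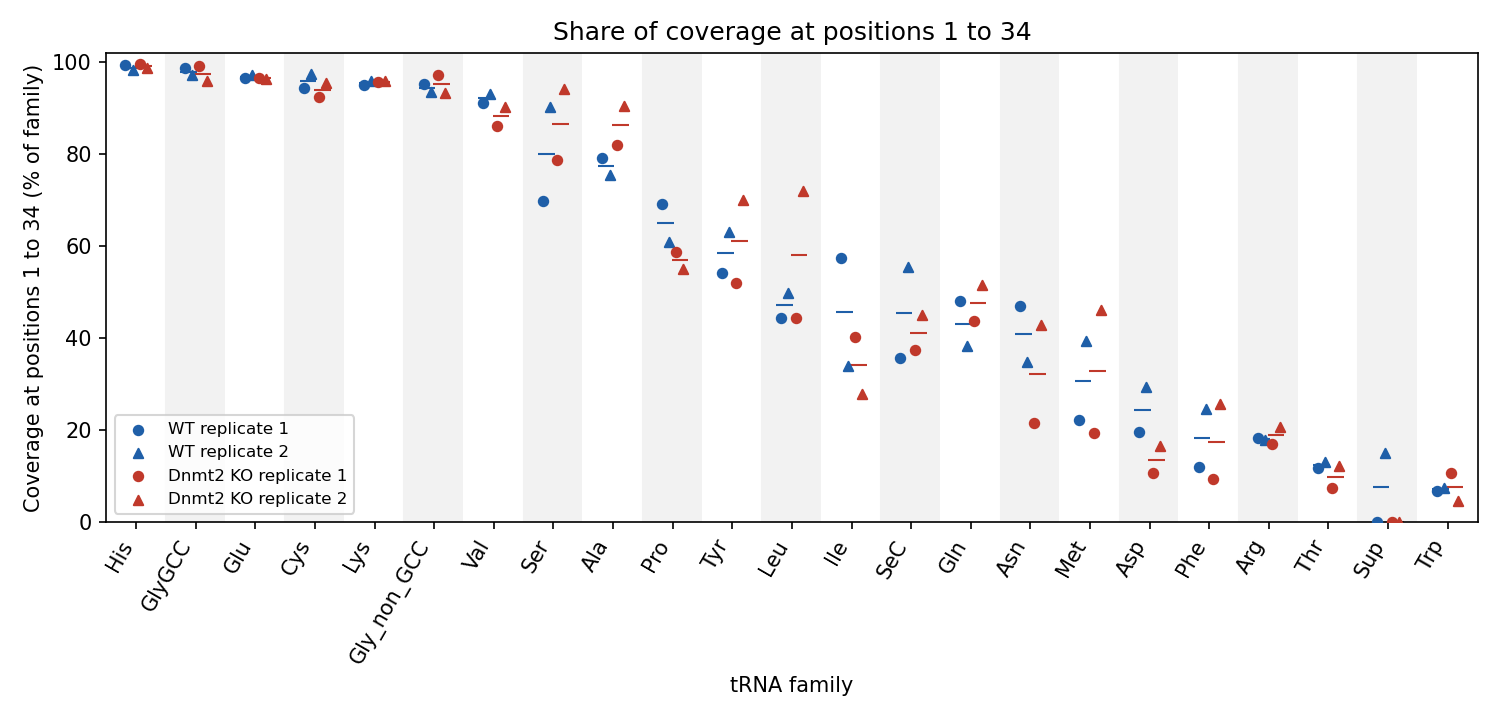
Share of the forward-strand coverage of each of 23 families that lies at positions 1 to 34, in percent, for each library. Points are single libraries and short lines the means of 2 libraries. Families such as His and GlyGCC lie above 95% in each library, Asp lies between 10.5% and 29.5%, and Sup rests on 1 to 5 reads at its peak per library.

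Single positions were compared to see where along a tRNA the genotypes differed. GlyGCC coverage peaked at position 23 in both genotypes, Val at position 13, Gly_non_GCC at position 19, His at position 24, Glu at position 25, Gln at position 28, Ala at position 12, Phe at position 54 and Sup at position 58. Asp peaked at position 47 in WT, at 0.0722 units, and at position 48 in Dnmt2 KO, at 0.110 units (means, n = 2). The position of Asp named by the rule was position 1, with 0.0165 units in WT and 0.00976 in Dnmt2 KO, from 464 to 1765 reads per library. In GlyGCC it was position 65, with 0.000850 and 0.00233 units, in Val position 72, with 0.00457 and 0.00885 units, and in Gly_non_GCC position 72, with 0.000492 and 0.000977 units. These rest on 69 to 134 reads per library in GlyGCC, far below its peak, 344 to 497 in Val and 31 to 86 in Gly_non_GCC. In His it was position 34, with 0.0194 and 0.0589 units (1132 to 3584 reads), and in Gln position 57, with 0.00124 and 0.00406 units (104 to 220 reads).

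With limma, 0 of 1656 positions passed the threshold (lowest adjusted p = 0.999), and 0 had an unadjusted p under 0.05. The error of this fit holds the shift between replicate numbers, at which 523 positions passed limma's threshold. These counts of 0 are therefore no evidence that the positions are alike. With the replicate number as a block, 0 positions passed as well (lowest adjusted p = 0.366). The log2 difference was −0.80 (SE 0.77) at Asp position 1, 1.13 (SE 0.91) at GlyGCC position 65, 0.92 (SE 0.89) at Val position 72, 0.84 (SE 0.67) at Gly_non_GCC position 72, 1.44 (SE 1.17) at His position 34 and 1.56 (SE 0.88) at Gln position 57. For the remaining named positions it was 0.83 at Ala position 40, 0.97 at Phe position 55, −0.19 at Sup position 56 and 0.98 at Glu position 69. With each family rescaled to one total, which takes out the difference of the family total, it was 0.20 at His position 34, 0.46 at Gln position 57, 0.34 at Gly_non_GCC position 72, 0.71 at GlyGCC position 65, 0.17 at Phe position 55 and −0.0050 at Ala position 40. Without Dnmt2 KO replicate 2 the difference as deposited was 0.18 at His position 34, 0.16 at GlyGCC position 65, 0.15 at Val position 72, 0.19 at Ala position 40 and 0.18 at Glu position 69. As deposited, 1383 estimates were above 0 and 273 below. Both Dnmt2 KO libraries lay above both WT libraries at 283 positions and below at 5. Together these are 17.4% of positions, where exchangeable libraries would give 33.3%. The shift between replicate numbers adds overlap here too, so the low share is no evidence that the genotypes are alike. Neighbouring positions share reads, so these counts are descriptive.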

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

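Counts of 0 past the threshold held for the 5′ share and for single positions under each alternative run, and for family totals and the loop share under each except the replicate block. Of the 549 estimates recomputed under an alternative, 41 turned sign and 5 newly passed the threshold, and 503 kept both. The cause of the turns was not tested beyond the construction of each alternative (fewer libraries, another window or another scaling). The added alternatives (row labels, variance trend, positions without coverage, scaling of the comparison of replicate numbers) were chosen after seeing the data. Leaving out a library leaves 1 library in a genotype, which is assumed to vary like the others.

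With the replicate number as a block (replicate block), 2 families passed for totals, His (log2 difference 1.25, adjusted p = 0.0324) and Gln (1.17, adjusted p = 0.0324), and 1 for the loop share, Phe (−0.93, adjusted p = 0.00386), whose loop coverage lies below the pseudocount. Over the other alternatives the lowest adjusted p from limma lay between 0.529 and 0.996 for totals and between 0.142 and 0.946 for the loop share. The labels do not say that a number marks a shared animal, litter or day, so this fit is a hint only. Deviations of the same-numbered libraries from their genotype means correlated at 0.862 across families, which are not independent replicates.

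Leaving out single libraries gave these ranges of log2 differences for totals: Val −0.99 to 1.17, Ala −0.26 to 2.01, Sup −0.47 to 0.21, Glu −0.96 to 0.79, the substrate set −0.14 to 0.80, the set often seen as 5′ fragments −0.32 to 1.15, the long variable arm set −0.40 to 1.54 and the inosine set −0.47 to 1.48. For the loop share they were −0.16 to 0.015 for Val, −0.14 to 0.64 for Gln, −0.040 to 0.23 for Lys, −0.94 to 0.22 for Ser and −1.06 to 0.41 for Trp. For the 5′ share they were −1.10 to 1.28 for GlyGCC, −0.27 to 1.07 for Gly_non_GCC, −0.32 to 1.79 for Ser, −0.16 to 1.53 for Leu, −0.31 to 1.20 for His and −0.71 to −0.36 for the substrate set, which among these passed fry's threshold only without Dnmt2 KO replicate 1. Position 56 of Sup ranged from −0.40 to 0.010. Others kept their sign over wide ranges: totals of Gln 0.37 to 1.96, His 0.77 to 1.74 and Asp 0.18 to 0.66, the queuosine set 0.088 to 1.31, the loop share of GlyGCC −0.53 to −0.0090 (the latter without Dnmt2 KO replicate 1), of Asp −0.43 to −0.18, of Gly_non_GCC −0.37 to −0.041, of Leu −0.57 to −0.11, of Tyr 0.19 to 0.53 and of the substrate set −0.35 to −0.085, the 5′ share of Asp −1.45 to −0.66, of Val −0.93 to −0.35, of Ala 0.41 to 1.49, of Ile −1.38 to −0.0050 and of Cys −1.21 to −0.078, position 1 of Asp −1.36 to −0.23, position 65 of GlyGCC 0.16 to 2.10, position 34 of His 0.18 to 2.71, position 72 of Val 0.15 to 1.68, position 72 of Gly_non_GCC 0.53 to 1.15, position 57 of Gln 0.75 to 2.36, position 40 of Ala 0.19 to 1.47, position 55 of Phe 0.50 to 1.44 and position 69 of Glu 0.18 to 1.78.

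With libraries rescaled to one total, Val was at −0.27, the substrate set at −0.038 and the queuosine set at 0.34. With one median family, the queuosine set was at 0.27, Asp was at −0.019, Val at −0.35, the substrate set at −0.11 and the set often seen as 5′ fragments at −0.023. The larger pseudocount put the loop share of Tyr at −0.089, and the window at positions 34 to 40 put that of Asp at 0.017, Val at 0.079 and Lys at −0.028. The window at positions 1 to 30 gave the substrate set a 5′ share mean of −0.44, past the threshold, against a range of −0.85 (set without GlyGCC) to −0.28 (set without Asp) over its alternatives. Row labels read from 0 put the loop share of Val at 0.0031. Each family rescaled to one total put position 40 of Ala at −0.0050, position 34 of His at 0.20, position 57 of Gln at 0.46, position 55 of Phe at 0.17 and position 72 of Gly_non_GCC at 0.34. The count of families past the threshold between replicate numbers was 15 as deposited, 10 with one total and 5 with one median family. Depth limits Sup, with 1 to 5 reads at its peak, and Phe, with 32 to 143, more than GlyGCC, with at least 88444.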

Other observations

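The tests of read shares at positions 10 and 45 of Asp, of the median over the other families, of the shifts between replicate numbers and of the coverage left at position 34 were chosen after the values they measure had been seen, whereas the limma comparisons of totals and of the 5′ share between genotypes were planned, and their use to weigh an explanation was not. The families split by where their coverage lay. In 7 families (Cys, Glu, Gly_non_GCC, GlyGCC, His, Lys and Val) the mean 5′ share over the 4 libraries was above 85%. Trp, at 7.15% ± 0.494 in WT and 7.64% ± 4.40 in Dnmt2 KO (SD, n = 2), Thr, at 12.4% ± 0.884 and 9.79% ± 3.40, and Arg, at 18.1% ± 0.308 and 18.8% ± 2.68, were seen mostly as 3′ fragments, as was Asp. Reverse-strand coverage was low, at 0.0302% ± 0.00168 of all coverage in WT and 0.0194% ± 0.00249 in Dnmt2 KO.

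Asp at position 10 had 0.541 times the WT coverage in the Dnmt2 KO library of number 1 and 0.638 times in that of number 2, and it stayed below 1 with libraries rescaled to one total (0.431 and 0.481) or one median family (0.492 and 0.381). At position 45 it had 1.40 and 1.64 times as deposited and 1.12 and 1.24 times with one total, but 1.28 and 0.979 times with one median family, so the direction there depends on the scaling. Counting depth alone is argued against, since the exact 95% intervals of the read share of position 10 (15.3% and 22.5% in WT, 6.53% and 10.2% in Dnmt2 KO) left a gap of 3.66 percentage points between the genotypes. A like loss of 5′ coverage in all families is argued against by the median log2 odds difference of 0.000959 in the other 22 families (SD 0.47). Asp was picked as the largest estimate, so its distance from the others is no evidence. Of the families with a WT 5′ share below that of Asp, Thr (−0.43), Phe (−0.28), Trp (−0.16) and Sup (−0.060) were below 0 and Arg (0.062) above. A smaller loss confined to such families is not argued against. An effect of genotype may underlie the lower 5′ share of Asp, as Asp is a Dnmt2 substrate. This remains open because the 95% limma interval of the Asp difference reaches up to 0.35 and the WT libraries differ from each other too. Of the other substrates, Val had Dnmt2 KO to WT ratios of the 5′ share of 0.945 and 0.969 in numbers 1 and 2, and GlyGCC had 1.01 and 0.987.

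More families passed the test between replicate numbers than between genotypes, each fitted as the sole term. The error of the genotype fit (median SE 0.84) therefore held the shift between numbers, so the counts are not like for like. With the replicate number as a block, 2 families passed between genotypes, as given above. Between libraries numbered 2 and 1, 15 families passed limma's threshold as deposited, all 15 higher in number 2 where the median log2 shift of the 23 families was 1.20 (SE of a family 0.49), 10 with one total (8 higher and 2 lower) and 5 with one median family (Asp, GlyGCC, Gly_non_GCC, His and Phe, all 5 lower), against 0 between genotypes under each scaling (also 0 at an unadjusted p under 0.05). As deposited, Lys in number 2 was 2.86 times that in number 1 in WT and 4.78 times in Dnmt2 KO, and Leu 2.98 and 5.01 times, while GlyGCC was at 1.17 and 1.14 times and Gly_non_GCC at 0.890 and 0.957 times. One scaling constant per library as the whole cause is argued against by the families still past the threshold after either rescaling (at least 5), but which families moved, and in which direction, depends on the scaling. Too few reads are argued against by 5 families with at least 1000 reads in every library past the threshold as deposited (Ala, Gln, Glu, Lys and Val). With one median family these did not pass limma's threshold (lowest adjusted p = 0.356, for Gln). Those that passed there included Asp, GlyGCC, Gly_non_GCC and His, with at least 4506 reads at the peak in every library. No biological explanation was tested.

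In families seen as 5′ fragments, the coverage left at position 34 was taken as a share of that at position 28. Position 34 lies only approximately at the anticodon, and fragments that end before position 28 do not enter. The share was 42.6% ± 3.52 in WT and 32.3% ± 0.402 in Dnmt2 KO for Val, 49.5% ± 2.74 and 41.4% ± 1.78 for Glu, and 19.1% ± 7.00 and 11.5% ± 6.67 for GlyGCC (SD, n = 2). With limma, 0 of 7 families passed the threshold and 0 had an unadjusted p under 0.05. Counting depth is argued against for Val and Glu, the 2 families whose exact 95% intervals in Dnmt2 KO lay wholly below those of both WT libraries, and in 4 families (also Cys and GlyGCC) they did so within each number. Shorter inserts throughout the Dnmt2 KO libraries could lower the share in every family, and 5 of 7 had a lower mean, while Lys (45.3% ± 2.27 and 45.9% ± 1.31) and His (19.0% ± 15.6 and 20.6% ± 13.5) did not. Insert length and genotype cannot be told apart here, because each genotype has 2 libraries and the lower means were not confined to the substrate set. Outside that set, Glu, Cys (25.8% ± 10.4 and 17.5% ± 7.68) and Gly_non_GCC (10.1% ± 1.58 and 6.71% ± 1.61) had lower means, while Lys and His did not.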
